A study of Mus musculus with 6 samples.

How the data were processed

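Gene expression was measured on 6 Affymetrix mouse whole-genome expression arrays, 3 hybridised with RNA from wild-type (WT) CD4 T cells and 3 with RNA from SAP-deficient CD4 T cells, all cultured under Tfh-like conditions. Genotypes were taken from the sample labels. Replicates were numbered 1 to 3 within each genotype, and the labels state no pairing between equal numbers. Per the labels' protocols, 500 ng of total RNA was labelled for each array.

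The deposited values are log2 expression levels of 45101 probe sets, with 1 column per array and no pooling of replicates. Per the submitters' processing notes, the authors used Affymetrix Expression Console and RMA, a method that corrects background, equalises the distributions of the arrays and summarises the probes of each probe set on the log2 scale. The versions, the genome build and the annotation used upstream are not given in the sources used here. RMA compresses differences of dim probe sets, so a fold change that ends near background can be understated. Its equalised distributions also hide any change in the total amount of RNA per cell. The array medians ran from 5.73 to 5.77 and no 2 arrays shared more than 63 equal values, so none was a copy of another.

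From these values, 64 control probe sets were left out and 45037 were tested. The platform annotation supplied with the values gives 1 gene for 34945 of the probe sets, several for 932 and none for 9160. Symbols were updated through a RefSeq gene table, which matched 34741 of the probe sets with 1 gene. Each of 18193 genes was represented by its single-gene probe set with the highest mean over the 6 arrays. SAP-deficient arrays were compared with WT arrays by limma (version 3.58.1, R version 4.3.3), with lmFit on genotype alone and eBayes with an intensity trend. Changes are SAP-deficient minus WT on the log2 scale. P-values were adjusted by the Benjamini-Hochberg method, over probe sets and over genes separately, and a call needed an adjusted p under 0.05. Intervals are 95% intervals of the same fit. Simulated data showed how much this fit can detect. They kept the means of the matched pairs of arrays described below, with random spread taken from the fit with these pairs as a block. Each of 5 draws held 200 changed genes among 18193, and a list of 25 further genes raised by 0.3, whose calls were not counted. The genotype-only fit recovered 2.69% of changes of 0.5 log2 units, 69.9% of changes of 1 and 95.2% of changes of 2. It made 0 calls among unchanged genes.

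Before the data were examined, 28 gene lists with 601 genes were fixed, of which 534 genes were measured: Tfh programme, non-Tfh effector and homing, SLAM receptors and SAP signalling, Th1, Th2, Th17, Treg, TCR-induced early genes, co-inhibitory receptors, IL-6 and IL-21 STAT3 targets, interferon response, cell cycle, apoptosis, glycolysis and hypoxia, cholesterol synthesis, unfolded protein and amino acid response, heat shock, chromatin regulators, B cells, antigen-presenting and myeloid cells, MHC class II, neutrophils and mast cells, NK, NKT and CD8 T cells, erythroid and platelet, T cell identity, ribosomal proteins, immediate cell handling and RNA stress, and Y-linked genes with Xist. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01 between its genes, adjusted over the lists. Camera with the correlation estimated from the arrays and limma's fry were run beside it. The 25 measured genes on each side of Sh2d1a in the RefSeq table were tested in the same way, because a gene targeted in embryonic stem cells can keep flanking DNA of the donor strain.

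The genes named in the text were also fixed by a rule before the data were examined. The rule takes Sh2d1a; in each direction the 15 called genes with the largest change or, where fewer than 5 are called, the 5 with the smallest p-value, given as values; called members of the lists; Bcl6, Cxcr5, Pdcd1, Icos and Il21 of the Tfh list; the regulators Tbx21, Gata3, Foxp3 and Prdm1; and the genes of the sex list. A further item of this rule is not reported here. Members of other lists named below were chosen after their values were seen, to show the size of a list's shift.

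Alternatives fixed in advance were eBayes without the trend and with robust variance, 2 filters on dim probe sets, a second quantile normalization, centring on array medians, array weights, other probe sets to stand for a gene, other set tests and the removal of each array in turn. A further alternative was chosen after seeing the data, because arrays of opposite genotype resembled each other in pairs. Pairs were matched on odd-numbered probe sets and checked on even-numbered ones. There the deviations from the genotype means correlated at 0.54, 0.73 and 0.60 within the 3 matched pairs and at most at -0.11 between other arrays of opposite genotype. Deviations from a mean of 3 arrays sum to 0, so high values within pairs push the other correlations below 0. Odd and even probe sets come from the same arrays, so the check is not independent evidence of pairing. The matched arrays carried the same replicate number, but the labels state no pairing. The pairs were therefore entered as a fixed block, or as a random block through limma's duplicateCorrelation, only as alternatives. P-values of the blocked fits do not count the choice of the matching. The simulated data hold the pairs by construction. In them the fixed block, with the same number of arrays, recovered 90.7% of changes of 0.5 log2 units. Leaving out calls on the 25 genes raised by 0.3, 9.01% of its calls fell on unchanged genes, above the nominal rate. There the low recovery of the genotype-only fit came largely from leaving the pairs out.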

Results

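Expression was profiled in CD4 T cells that carry the OT-II T cell receptor transgene, which recognises an ovalbumin peptide presented on MHC class II. The cells were either WT or lacked SAP, the small adaptor protein encoded by Sh2d1a that relays signals from SLAM-family receptors. Naive cells were sorted and grown for 3.5 days with ovalbumin peptide and with splenocytes that had been depleted of T cells and treated with mitomycin C to stop their division. The medium held the cytokines IL-6 and IL-21, at 100 and 50 ng/ml, and antibodies that block IFN-γ, IL-12, IL-4 (10 µg/ml) and TGF-β (20 µg/ml), a mixture meant to steer T cells toward follicular helper T (Tfh) cells, the subset that helps B cells in germinal centres. Each genotype was represented by 3 arrays. The design asks which transcripts of such Tfh-like cells depend on SAP. The labels do not say whether the 3 arrays of a genotype came from separate mice or cultures, so p-values measure only the spread between these arrays, part of which may be technical. The sex-linked transcripts given below differ between them, so they were not repeat arrays of 1 RNA sample.

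Most of the variation between arrays did not follow genotype. Each WT array resembled 1 SAP-deficient array more than it resembled any other WT array: the correlation over all probe sets was 0.996 to 0.998 within the 3 matched pairs and 0.989 to 0.994 between arrays of the same genotype. The first principal component held 58.0% of the variance of the 5000 most variable probe sets and the second 27.5%, and 99.6% and 97.9% of their scores lay between the matched pairs. Over all probe sets, the pairs held 73.4% of the variance and genotype 9.61%. Transcripts of the sex chromosomes differed in the same way. Xist, the non-coding RNA that silences an X chromosome in female cells, was at 12.50 (log2) in replicate 1 of both genotypes, at 8.21 and 8.19 in replicate 2 of WT and SAP-deficient cells, and at 5.81 and 6.26 in replicate 3. The Y-linked gene Eif2s3y was at 3.54 and 2.91 in replicate 1, at 9.96 and 9.98 in replicate 2, and at 9.80 and 9.76 in replicate 3. Between genotypes, Xist differed by 0.14 (95% interval -4.24 to 4.52), Eif2s3y by -0.22 ± 2.22 (SE), Kdm5d by 0.05 ± 1.75 and Uty by -0.28 ± 0.79, all with an adjusted p of 1.00.

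**Figure D1:**
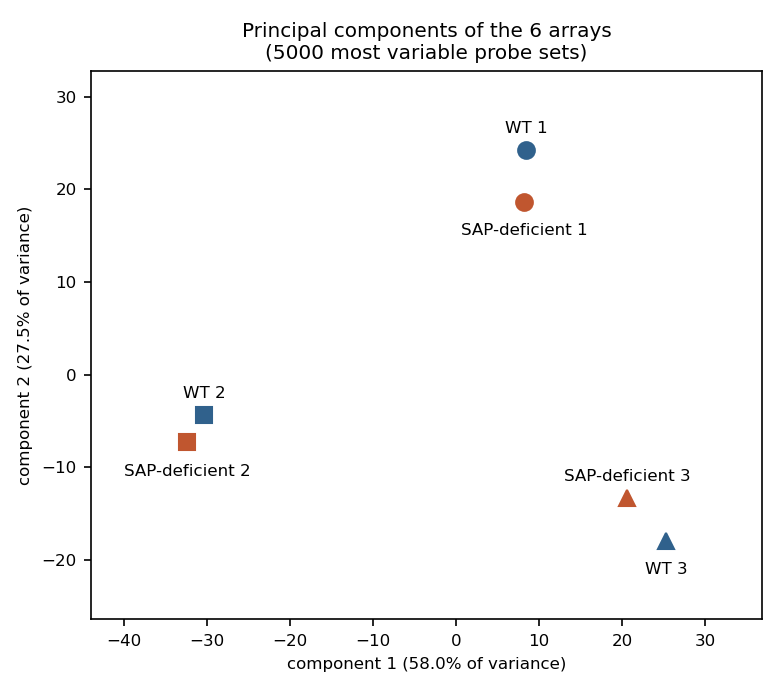
Scores of the 6 arrays on the first and second principal components (58.0% and 27.5% of the variance) of the 5000 most variable probe sets; blue, WT; orange, SAP-deficient; symbols mark replicates 1 to 3. Arrays lie beside the array of the other genotype with the same replicate number, though the labels state no pairing.

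The targeted transcript was low in every SAP-deficient array. Sh2d1a (Entrez Gene 20400, X chromosome, measured by 1 probe set) was at 9.14 ± 0.53 in WT cells and at 4.83 ± 0.69 in SAP-deficient cells (log2, SD, n = 3 arrays each), a 19.8-fold lower level. The change was -4.31 with a 95% interval of -5.17 to -3.45. The highest SAP-deficient value, 5.47, lay far under the lowest WT value, 8.52, and the differences within the matched pairs were -4.03, -4.42 and -4.47. Its adjusted p was 0.0501 over genes (limma), just above the threshold of 0.05, and 0.124 over probe sets. With the matched pairs as a block, an alternative chosen after seeing the data, the adjusted p was 1.99e-07 over genes and 4.92e-07 over probe sets. Where this probe set lies relative to the targeted part of the gene is not known here.

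By the probe set that stands for each gene, no other gene differed by 2-fold or more, and none reached the threshold. Limma called 0 of 18193 genes and 0 of 45037 probe sets, and 239 genes (1.31%) had an unadjusted p under 0.05, of which 103 were higher and 136 lower in SAP-deficient cells. With the matched pairs as a block, 1110 genes (6.10%) had an unadjusted p under 0.05 and 1 gene, Sh2d1a, was called. After Sh2d1a, the lower genes with the smallest p-values were Rnase2b (-0.38 ± 0.09, SE), the chemokine gene Xcl1 (-0.59 ± 0.14), Odam (-0.29 ± 0.08) and the lipid transporter gene Abca8b (-0.39 ± 0.10). Among higher genes the smallest p-values belonged to the cell-cycle inhibitor gene Cdkn2a (0.40 ± 0.10), the steroid-metabolising enzyme gene Akr1c18 (0.39 ± 0.11), the melanocortin receptor accessory gene Mrap (0.35 ± 0.10) and Fam221b (0.40 ± 0.11). A gene with only a clone name, 1700123M08Rik, was at 0.34 ± 0.09. All of these had an adjusted p of 1.00, and all but Xcl1 and Akr1c18 were dim, with mean levels from 2.66 (Odam) to 4.94 (Cdkn2a) against a median probe-set mean of 5.75. Xcl1 and Akr1c18 were well expressed, with mean levels of 10.67 and 9.47, and every SAP-deficient array lay beyond every WT array for both. If all arrays were exchangeable, 3 against 3 would reach such an order by chance in 10% of genes. The arrays resembled each other in pairs, so that rate need not hold here.

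**Figure D2:**
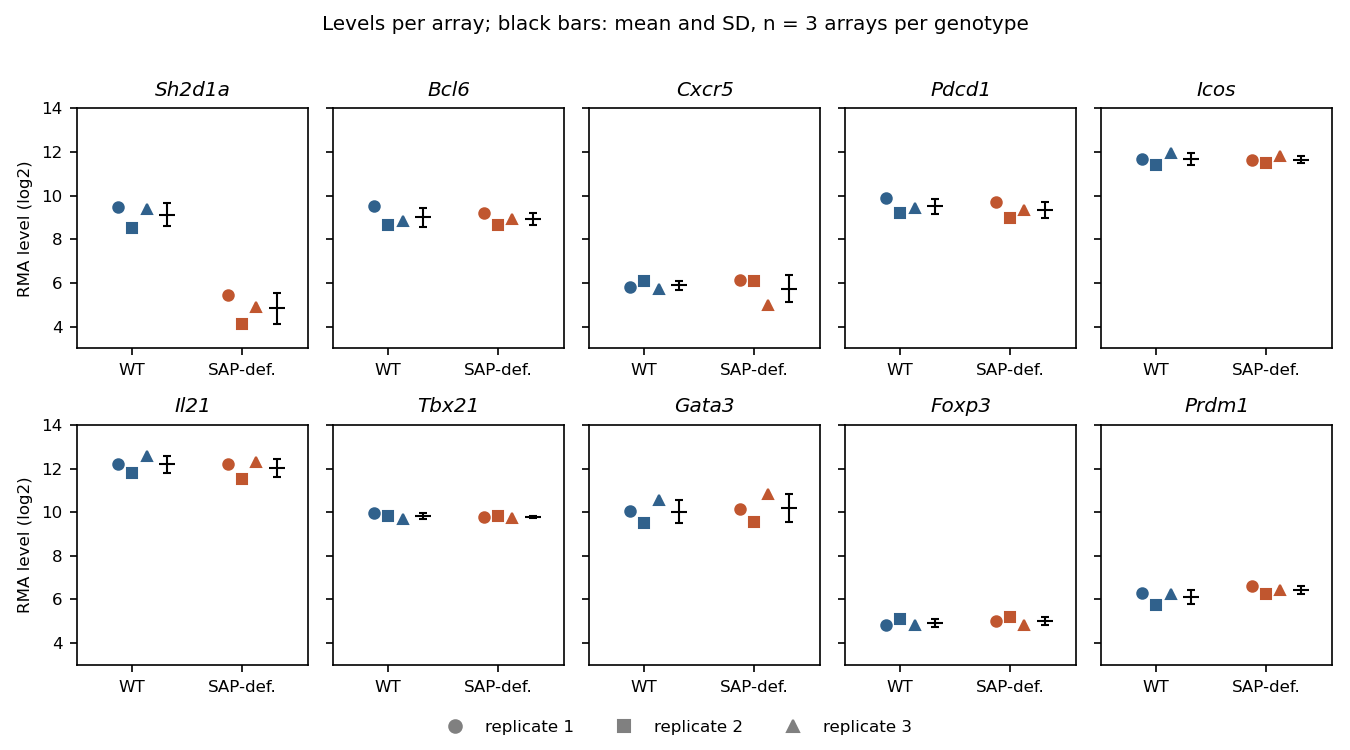
RMA levels (log2) per array of Sh2d1a, 5 Tfh genes and 4 lineage regulators; blue, WT; orange, SAP-deficient; symbols mark replicates 1 to 3, and black bars give the mean and SD of the 3 arrays. The genotypes stand apart for Sh2d1a (means of 9.14 and 4.83) and overlap in the other panels.

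Genes of the Tfh programme did not differ detectably between the genotypes in the genotype-only fit. Of the 28 measured genes of this list, 12 were higher and the median change was -0.06 (camera adjusted p = 0.813; 0.977 with an estimated correlation). None was called over all genes, and none when adjusted over the list alone. Bcl6, the transcriptional repressor that directs Tfh differentiation, changed by -0.07 with a 95% interval of -0.62 to 0.48. A second, dimmer Bcl6 probe set was at 0.26 ± 0.22 (SE), with 0.18, -0.04 and 0.63 within the matched pairs. The chemokine receptor gene Cxcr5, which guides T cells to B cell follicles, was at -0.15 (-0.81 to 0.51). Pdcd1, encoding PD-1, was at -0.17 (-0.70 to 0.36), the costimulatory receptor gene Icos at -0.03 (-0.36 to 0.30) and the cytokine gene Il21 at -0.18 (-0.73 to 0.37), each with an adjusted p of 1.00. Within the matched pairs, Pdcd1 was lower by -0.20, -0.22 and -0.08 and Il21 by -0.01, -0.25 and -0.28, with adjusted p-values of 0.800 and 0.722 in the blocked fit. In that fit 4 genes of the list were higher and 6 lower at an unadjusted p under 0.05, and 1 higher (Il4) and 1 lower (Tnfsf8) were called when adjusted over the list alone. Fry's mixed test, which ignores direction, gave the list an adjusted p of 0.0442 with the block and 0.932 without it.

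Among the lists of T helper lineages, that of Th2 cells shifted relative to other genes. Its 18 measured genes had a median change of 0.12, and 13 were higher in SAP-deficient cells (camera adjusted p = 0.0397); with an estimated correlation the adjusted p was 0.977. The largest differences were in cytokine and chemokine genes, with Il13 at 0.55 ± 0.47 (SE), Ccl1 at 0.47 ± 0.41, Il4 at 0.40 ± 0.55 and Il24 at 0.33 ± 0.41, while Gata3, the Th2-directing transcription factor, was at 0.15 ± 0.34. Without SAP-deficient replicate 3 these 5 changes were 0.05, 0.09, -0.04, -0.02 and -0.17. Without WT replicate 2 Il4 was at -0.07 and Gata3 at -0.11. Leaving out 1 array unbalances the matched pairs, so differences between pairs enter such values, the list medians below included. Il4 had mean levels of 10.83, 9.65 and 11.51 in pairs 1 to 3, against changes of 0.52, 0.23 and 0.44 within them. None of the 18 genes was called, either over all genes or adjusted over the list alone; with the pairs as a block 4 were called over the list alone, Ccl1, Il4, Il13 and Il24, all higher. The mean change was 0.10, 0.12 and 0.24 within the 3 matched pairs, and the blocked adjusted p was 6.37e-05, or 0.666 with an estimated correlation. In pair 3, where the Th2 mean was highest, MHC class II genes had a mean of -0.47, B cell genes one of -0.23 and cell-cycle genes one of 0.52. The call was lost without WT replicate 1 (median 0.13, adjusted p = 0.0894), WT replicate 2 (0.07, 0.682) or SAP-deficient replicate 3 (0.003, 0.903), and when probe sets under the median (0.10, 0.241) or the 75th percentile (0.12, 0.267) were left out.

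The other lineage lists held both higher and lower genes. Th1 genes had a median of 0.03 with 11 of 20 higher, and Tbx21, the Th1-directing factor, was at -0.06 ± 0.11. Th17 genes had a median of -0.01 with 8 of 17 higher. Treg genes had a median of 0.02 and a mean of -0.02 with 8 of 16 higher, and the Treg factor gene Foxp3 was at 0.10 ± 0.14. Non-Tfh effector and homing genes had a median of 0.05 with 13 of 18 higher (adjusted p = 0.0779), among them Prdm1, the antagonist of Bcl6, at 0.33 ± 0.19. With the pairs as a block this list's adjusted p was 0.0345, and 0.666 with an estimated correlation. It was also called without WT replicate 3 (median 0.10, adjusted p = 0.00485) or SAP-deficient replicate 1 (0.08, 0.00822). Targets of STAT3 downstream of IL-6 and IL-21 had a median of 0.08 with 12 of 20 higher (adjusted p = 0.0528; blocked, 0.0345, or 0.666 with an estimated correlation). They were also called without WT replicate 1 (0.11, 0.0290) or 3 (0.06, 0.0378), without SAP-deficient replicate 1 (0.06, 0.0334) or 2 (0.18, 0.0120), and without _x_at and _s_at probe sets (0.08, 0.0420). Th1 genes were called without WT replicate 3 (0.10, 0.0397).

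On average over the arrays, genes of cholesterol synthesis were higher in SAP-deficient cells throughout the list. All 24 measured genes lay above 0, with a median of 0.12 and an SD between genes of 0.06 (camera adjusted p = 8.97e-05); with an estimated correlation the adjusted p was 0.686. Hmgcs1, which makes the precursor of mevalonate, was at 0.25 ± 0.19 (SE), the mevalonate pathway kinase gene Pmvk at 0.24 ± 0.17, Lss, which forms lanosterol, at 0.23 ± 0.16, and Sqle, encoding squalene epoxidase, at 0.14 ± 0.16. No gene of the list was called on its own or had an unadjusted p under 0.05 in the genotype-only fit (limma). Of the 24, 14 were higher in all 3 matched pairs. Means within the matched pairs were 0.08, 0.11 and 0.20, the last in pair 3, where MHC class II genes had a mean of -0.47, B cell genes one of -0.23 and cell-cycle genes one of 0.52. Without WT replicate 3 the median was 0.08 and the adjusted p 0.0680; over all alternatives the median ran from 0.05 to 0.19.

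Cell-cycle genes were higher on balance in the comparison of all arrays, but this rested on the third replicates. Of 39 measured genes 34 were higher, with a median of 0.09 (camera adjusted p = 0.0174; 0.977 with an estimated correlation). The spindle checkpoint kinase gene Bub1b was at 0.28 ± 0.22 and cyclin A2 (Ccna2) at 0.19 ± 0.19. Within the matched pairs the list's mean was -0.18, -0.07 and 0.52, and in pair 3 the MHC class II mean was -0.47 and the B cell mean -0.23. Without WT replicate 3 the median turned to -0.10 (adjusted p = 1.61e-04), and it was 0.08 without SAP-deficient replicate 2 (0.236) and 0.05 without SAP-deficient replicate 3 (0.330). With array weights it was -0.01 (0.842), after a second quantile normalization 0.06 (0.0600), and without probe sets under the 75th percentile 0.10 (0.152).

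Genes of the unfolded protein and amino acid response were slightly lower in SAP-deficient cells. Of 30 measured genes 6 were higher, and the median was -0.07 (camera adjusted p = 0.0174; 0.977 with an estimated correlation). The stress-induced factor gene Ddit3 was at -0.23 ± 0.28 and the endoplasmic reticulum chaperone genes Calr and Hspa5 at -0.13 ± 0.10 and -0.08 ± 0.06. Within the matched pairs the mean was 0.02, -0.07 and -0.16, and in pair 3 the means of MHC class II, B cell and cell-cycle genes were -0.47, -0.23 and 0.52. The median turned to 0.06 without WT replicate 2 (adjusted p = 0.645) and to 0.05 without SAP-deficient replicate 3 (0.618), and was -0.05 with the mean of all probe sets of a gene (0.0589) and -0.02 in the block without pair 3 (0.115).

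Among the lists of markers of other cells that the culture could hold, which included the splenocytes presenting the peptide, those of MHC class II and B cells were lower in SAP-deficient arrays, mostly in replicate 3. MHC class II genes had a median of -0.26 with 1 of 9 higher (camera adjusted p = 0.00521; 0.686 with an estimated correlation). Among them were H2-Aa at -0.29 ± 0.30, H2-Eb1 at -0.31 ± 0.25 and the invariant chain gene Cd74 at -0.17 ± 0.14. B cell genes had a median of -0.13 with 4 of 18 higher (camera adjusted p = 0.0174, or 0.830 with an estimated correlation). Lower genes included Ebf1 at -0.42 ± 0.25 and Cd72 at -0.35 ± 0.17, while the only gene with an unadjusted p under 0.05 (limma) was higher. Apart from Ighm, the genes of this list lay under the 75th percentile of probe-set means (8.03). Several, such as Pax5, Cr2 and Fcer2a, lay under the median of 5.75. Means within the matched pairs were -0.05, -0.06 and -0.47 for MHC class II genes and -0.10, -0.01 and -0.23 for B cell genes. The MHC class II call was lost without WT replicate 3 (median -0.13, adjusted p = 0.0860) or SAP-deficient replicate 3 (-0.07, 0.292), and the B cell call without WT replicate 1 (-0.05, 0.522) or SAP-deficient replicate 3 (-0.06, 0.618). Antigen-presenting and myeloid genes had a median of -0.05 with 10 of 26 higher (adjusted p = 0.0544; blocked, 0.0345, or 0.666 with an estimated correlation). This list was also called without WT replicate 2 (-0.14, 0.00345) or SAP-deficient replicate 1 (-0.17, 1.66e-05), and in 4 further alternatives fixed in advance (-0.06 to -0.05, adjusted p from 0.00891 to 0.0424). Genes of T cell identity had a median of 0.02 and a mean of -0.02, with 10 of 17 higher; with the block, 2 lower genes (Cd28 and Trat1) were called over the list alone.

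**Figure D3:**
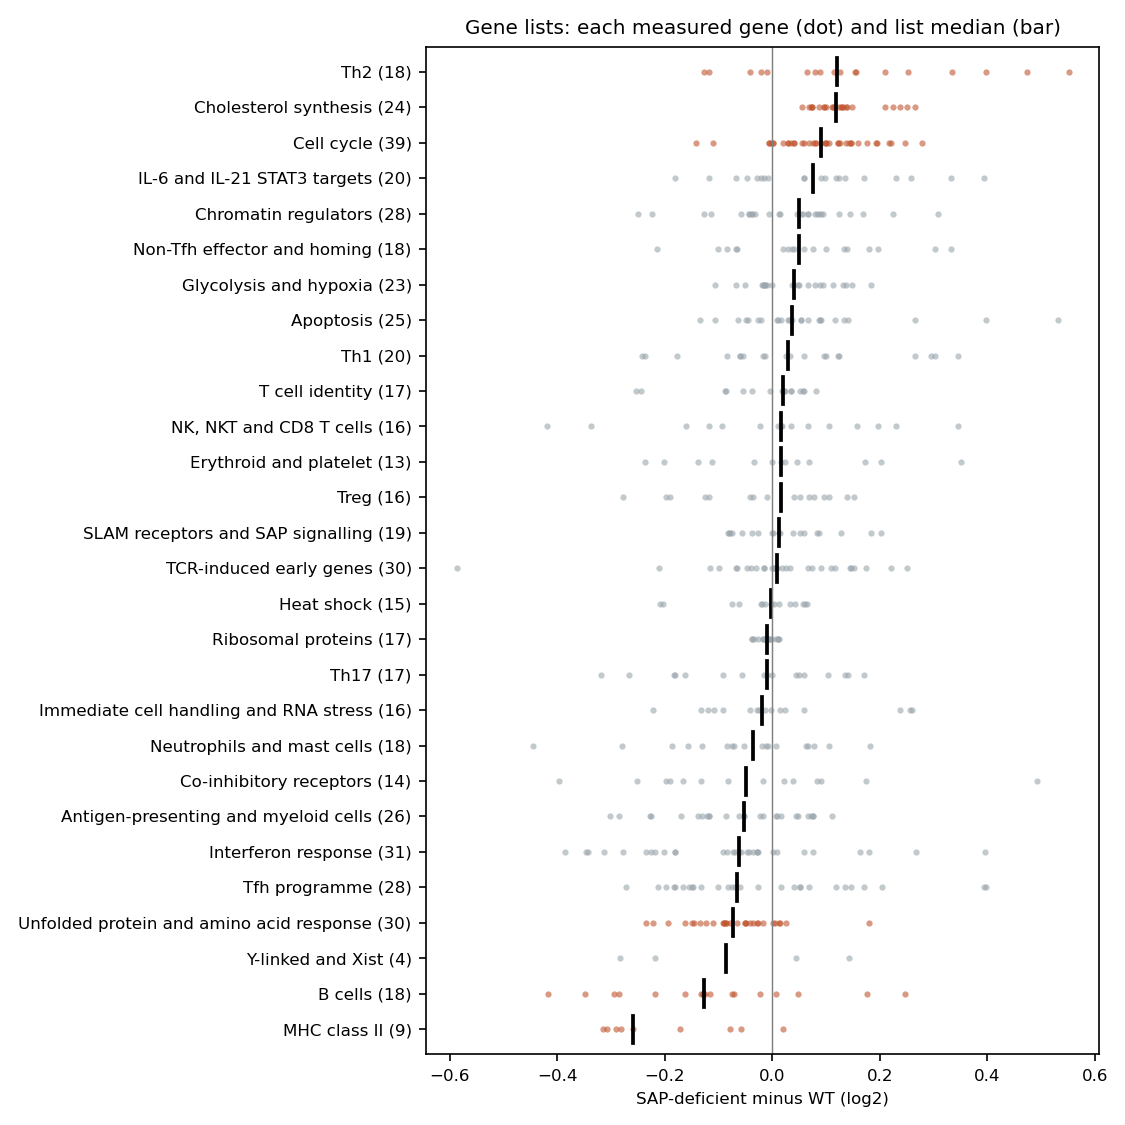
Change in SAP-deficient relative to WT cells (log2, horizontal axis) of each measured gene (dots) of the 28 lists, ordered by list median (black bars); numbers of measured genes are in brackets. Orange marks the 6 lists past the threshold with a preset correlation, with medians from -0.26 (MHC class II) to 0.12 (Th2 and cholesterol synthesis).

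The remaining lists did not pass the threshold in the comparison of all arrays. The SLAM receptors and SAP signalling list, the pathway SAP acts in, had a median of 0.01 with 12 of 19 genes higher. Genes induced early after T cell receptor stimulation had a median of 0.01 (19 of 30 higher) and co-inhibitory receptors one of -0.05 (6 of 14 higher). Interferon response genes had a median of -0.06 with 8 of 31 higher, apoptosis genes 0.04 with 18 of 25 higher, and genes of glycolysis and hypoxia 0.04 with 13 of 23 higher. With the pairs as a block the adjusted p was 0.0171 for the interferon, 0.0377 for the apoptosis and 0.0347 for the glycolysis list, and with an estimated correlation 0.730, 0.666 and 0.730. Leaving out single arrays moved several of these lists past the threshold. Interferon genes were called without WT replicate 1 (-0.23, 8.34e-06) or SAP-deficient replicate 2 (-0.16, 0.0101), with medians up to 0.09 in other alternatives. Glycolysis genes were called as higher without WT replicate 1 (0.14, 0.00116) or SAP-deficient replicate 2 (0.18, 5.90e-06) and as lower without WT replicate 2 (-0.09, 0.0255). Early T cell receptor genes were called as higher without WT replicate 3 (0.11, 0.00753) or SAP-deficient replicate 2 (0.18, 0.0216) and as lower without WT replicate 2 (-0.10, 0.0255). Such removals unbalance the matched pairs, so differences between pairs enter these values. Around their own mean, glycolysis genes lay at 0.19, -0.27 and 0.08 in pairs 1 to 3, and changed within them by 0.005, 0.02 and 0.09. For early T cell receptor genes these values were 0.04, -0.31 and 0.26, against 0.02, 0.04 and -0.03. Co-inhibitory receptors were called without WT replicate 2 (-0.17, 0.0304) or SAP-deficient replicate 1 (-0.15, 0.0171), and the SLAM list without SAP-deficient replicate 2 (0.15, 0.0291). Medians were -0.002 for heat shock genes (7 of 15 higher), 0.05 for chromatin regulators (17 of 28), -0.01 for ribosomal protein genes (4 of 17) and -0.02 for genes of cell handling and RNA stress (6 of 16), whose mean was 0.004. Ribosomal genes were called without probe sets under the 75th percentile (-0.01, 0.00458). Markers of neutrophils and mast cells had a median of -0.04 (6 of 18 higher; called without WT replicate 2, -0.09, 0.0263), those of NK, NKT and CD8 T cells 0.02 (10 of 16), and those of erythroid cells and platelets 0.02 (7 of 13). The 4 measured genes of the sex list had a median of -0.09. In all, 6 of 28 lists were called in the genotype-only fit and 12 with the pairs as a block, and 0 in either fit with an estimated correlation. The estimated correlation rests on 4 residual degrees of freedom, or 2 with the block, which leaves little power. Its 0 calls therefore cannot decide whether lists shifted. For the 6 called lists the estimates in the genotype-only fit ran from 0.233 (B cells) to 0.648 (cell cycle). With the block, those of the same lists ran from 0.060 (Th2) to 0.790 (cell cycle). All lay above the preset 0.01. Where genes of a list are correlated as strongly as estimated, the p-values at the preset correlation are too small. Fry called 0 lists in either fit in its directional form, and in its mixed form 0 in the genotype-only fit and 6 with the block: T cell identity (adjusted p = 0.0336) and the Tfh, non-Tfh, Th1, apoptosis and cell handling lists (0.0442). Adjusted over each list alone, no list gene was called in the genotype-only fit. With the block, besides the Tfh, Th2 and T cell identity lists, 2 co-inhibitory receptor genes were called as higher (Havcr2 and Cd160) and 4 as lower (Lag3, Ctla4, Cd200 and Btla), 4 non-Tfh genes as higher and 3 Th1 genes as higher, and 1 to 3 genes in each of 6 further lists.

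Genes beside Sh2d1a on the X chromosome showed no detectable shift as a set. The 50 nearest measured genes had a median change of 0.01, and 567 other X-linked genes had a median of -0.01. Camera gave an unadjusted p of 0.713 for the neighbours as a set. A median and a directional set test would miss single genes that moved in either direction. The largest absolute change was 0.34. At an unadjusted p under 0.05 (limma) there was 1 gene, and 3 with the pairs as a block, against 1.31% and 6.10% of all genes. None was called, but the genotype-only fit called 0 genes anywhere, so it could not have turned out otherwise there.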

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

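The fits with matched pairs as a block, alone or with a pair or the set test changed, were chosen after seeing the data; the other alternatives were fixed before. Genes called numbered 1 instead of 0 with robust variance, without _x_at and _s_at probe sets, with the pairs as a fixed block and as a random block, each time Sh2d1a, and 0 to 1 when single arrays were left out, the 1 without WT replicate 2. With the block and pair 1, 2 or 3 left out, 3, 1 and 37 genes were called. Probe sets called numbered 1 with the fixed or the random block, and 6, 3 and 40 without pair 1, 2 or 3. The change of the target gene Sh2d1a stayed at -4.31 with robust variance (adjusted p = 0.0405), without _x_at and _s_at probe sets (0.0493), with the block (1.99e-07) and with the random block (1.82e-04). It ran from -4.63 to -3.94 with single arrays left out, and was -4.45, -4.25 and -4.22 in the block without pair 1, 2 or 3, with an adjusted p from 2.26e-12 to 0.529 over all alternatives. Fewer genes tested explain the call without _x_at and _s_at probe sets, where the p-value did not change; for the others the cause was not tested. With the 75th percentile filter Sh2d1a had no value, because its mean level falls under it.

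Lists called numbered 6, and from 1 (without SAP-deficient replicate 3) to 10 (without SAP-deficient replicate 1 or 2) with single arrays left out, 12 with the block and 13, 9 and 5 in the block without pair 1, 2 or 3; the unfolded protein, B cell and MHC class II lists were not among the 5. They numbered 0 with camera's estimated correlation, with fry and with both the block and an estimated correlation, and 6 with the block and fry's mixed test. With single arrays left out, all 27 list genes that the report gives as examples moved by over 1.5 times and 13 of them turned. Some medians turned. Cell cycle genes turned to -0.011 with array weights and -0.13 in the block without pair 3, and ran from -0.10 (without WT replicate 3) to 0.19 with single arrays left out. Under such removal glycolysis and hypoxia genes ran from -0.091 (without WT replicate 2) to 0.18, TCR-induced early genes from -0.11 to 0.18 (-0.10 with a call without WT replicate 2), and the unfolded protein list from -0.15 to 0.061 (without WT replicate 2; 0.05 without SAP-deficient replicate 3). Leaving out a single array unbalances the matched pairs, so differences between pairs enter such values. How much of each turn this explains was not tested. With camera at the preset correlation the Tfh list stayed uncalled in every alternative (median -0.10 to 0.06, adjusted p from 0.0991 to 0.920), as did the genes beside Sh2d1a (-0.01 to 0.04). For the Tfh list an estimated correlation gave 0.977 and fry 0.990, but fry's mixed test with the block 0.0442. Of 1071 other values, 995 kept their direction and side of the threshold or were uncalled throughout, 51 gained a call, 18 lost one and 7 turned. Other scalings moved the median of all genes by less than 0.02. No detection calls were used, so a probe set near background has no lower bound on its level.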

Other observations

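The tests below with matched pairs as a block, and those of RNA degradation, of other cells, of DNA flanking Sh2d1a and of a variant under single probe sets, were chosen after the result was seen. With the pairs as a block no gene but Sh2d1a passed the adjustment; the genes named next are among those with the smallest p-values and were chosen after their values were seen. Ccl1, a chemokine gene of Th2-type cells, was higher in SAP-deficient arrays by 0.39, 0.63 and 0.41 within the 3 pairs (adjusted p = 0.0801), and Moxd1 by 0.52, 0.83 and 0.73 (0.0801). Rab4a, described below, was lower (0.105), and it was called in the block without pair 1 (-1.20, adjusted p = 0.0308) and without pair 3 (-0.92, 0.00801) but not without pair 2 (-0.86, 0.364). The neurotensin gene Nts was higher by 0.48, 0.43 and 0.62 (0.105), Havcr2, encoding the inhibitory receptor TIM-3, by 0.61, 0.52 and 0.34 (0.116), the itch cytokine gene Il31 by 0.91, 0.59 and 0.35 (0.147) and the pro-apoptotic gene Bcl2l11 by 0.42, 0.38 and 0.39 (0.173). Il4 was higher by 0.52, 0.23 and 0.44 (0.195) and Il13 by 0.34, 0.49 and 0.82 (0.272). Without pair 3 the block called 37 genes, among them Rab4a, Ccl1, Il24, Il31, Havcr2 and Bcl2l11.

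Between arrays of one genotype the same cytokine genes spread far more widely. Il31 was at 10.11, 8.63 and 11.94 in WT replicates 1 to 3 and at 11.02, 9.22 and 12.29 in SAP-deficient replicates 1 to 3. Il4 was at 10.57, 9.53 and 11.29 in WT and at 11.09, 9.76 and 11.73 in SAP-deficient arrays, and the inhibitory receptor gene Ctla4 at 12.15, 10.14 and 11.96 against 12.05, 10.02 and 11.61.

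The 6 arrays can be split into 3 and 3 in 10 ways, and all 10 splits, the real one included, gave as many called genes as the real one, which gave 0; the highest of the other splits also gave 0. With a real count of 0 every split had to reach it, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 239 genes and other splits up to 2931, which points to a structure of the samples other than genotype.

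The matching of arrays across genotypes, with pair correlations of 0.54 or more on probe sets not used to match, was not confined to the sex chromosomes. Over autosomal genes the lowest pair correlation was still 0.497. This cannot decide whether the sex of the donors is the cause, because sex can also act on autosomal genes. RNA degradation is argued against by control probe sets for the 3' and 5' ends of Gapdh and Actb, whose difference varied by at most 0.115 log2 units between arrays. A culture, donor pool or processing day shared by a WT and a SAP-deficient array could give such pairs and cannot be told apart from other causes (lowest correlation 0.541), since the labels name none. On the first component, replicate 2 lay at -30.3 (WT) and -32.4 (SAP-deficient), replicate 1 at 8.5 and 8.2, and replicate 3 at 25.3 and 20.6. Neither Xist, highest in replicate 1 and lowest in replicate 3, nor Eif2s3y, lowest in replicate 1, followed this order. That argues against sex as the whole cause of this component. On the second, replicate 1 stood apart at 24.3 and 18.6, so sex stays open as part of the pattern. Other differences between donors stay open as part or all of it.

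Higher expression of Th2 genes in SAP-deficient cells is a hypothesis from the preset-correlation test, and 0 lists were called with an estimated correlation. In pair 3, where the Th2 mean was highest (0.24), MHC class II genes had a mean of -0.47, B cell genes one of -0.23 and cell-cycle genes one of 0.52. The test of other cells assumes that fewer of them in the SAP-deficient cultures would raise all T cell transcripts alike. Within the 3 matched pairs the Th2 mean exceeded that of T cell identity genes by 0.11, 0.18 and 0.22 (95% interval 0.0294 to 0.312). On the 5 Th2 and 7 T cell identity genes whose probe sets were not used to match, the interval was 0.0373 to 0.731. This argues against such a change as the whole cause only if the pairs hold and the T cell identity genes register it. Whether they register it was not tested. The upper limit for T cell identity, tested earlier, was 0.0696 over the pairs, under the Th2 mean of 0.149. Over arrays without pairs it was 0.222, and there the interval of the difference also spans 0 (-0.54 to 0.88). Differences between cultures unrelated to genotype cannot be told apart from an effect of SAP: of the 4 ways to assign genotypes within the pairs, 1, the real one, gave a Th2 shift as large (absolute mean t statistic 1.92, highest other 0.649), too few ways for a share under 0.05.

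The same reassignments bear on the list counts of the blocked fit. The real assignment called 12 lists, and with pairs 2 and 3 swapped 10 lists were still called, with a camera p of 5.58e-05 for cholesterol synthesis and 0.0261 for Th2 genes (unadjusted), 1 called gene and 825 genes at an unadjusted p under 0.05 against 1110. With pair 2 or pair 3 alone swapped, 3 lists were called each time.

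Rab4a, a regulator of endosome recycling, and Itsn1, an endocytic scaffold, were singled out after their values were seen. Rab4a was lower in SAP-deficient arrays by -0.58, -1.27 and -1.14 within the pairs (blocked adjusted p = 0.105 over genes), and Itsn1, by the probe set that stands for it, by -0.66, -0.34 and -0.36 (0.445), though without _x_at and _s_at probe sets its change was 0.05. Donor-strain DNA around Sh2d1a is argued against, because 0 of the 2 genes lie on the X chromosome (Itsn1 is on chromosome 16, Rab4a on chromosome 8). Donor-strain segments elsewhere could not be settled: 6% of the 100 genes around both, 5 of 50 around Itsn1 (Mrap among them) and 1 of 50 around Rab4a, had an unadjusted p under 0.05 in the blocked fit against 6.10% of all genes (95% interval 2.23% to 12.6%). For Rab4a, the other probe set was lower by -0.70, -1.14 and -1.37 (upper 95% limit over the pairs -0.233). This argues against a sequence variant under single probe sets only if its probe sets read different stretches of the gene. Their positions were not known here. Such a variant may contribute for Itsn1. There, 1 of 3 other probe sets above the array median, and 4 of all 8, were lower in all 3 pairs (1 dim one, mean level 4.86, by -1.19).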
